A study of Homo sapiens with 4 samples.

How the data were processed

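The samples were 4 ATAC-seq libraries of LM2 cells: 2 with a non-targeting control guide and 2 with a CECR2 deletion made with guide sg1. Per the labels' protocols, 50000 cells per library were treated with the transposase and libraries were prepared by a published ATAC-seq protocol. The deposited table holds raw counts per peak for 190348 peaks, whose positions were identical to those of the deposited peak list. Per the file headers, the counts were made with featureCounts 1.6.0 in single-end mode on alignment files named as cut-site files, so a count stands for a transposase cut and a sequenced fragment can give a count at each end. Per the submitters' processing notes, CASAVA, Trimmomatic 0.39, Bowtie2, SAMtools, MACS2 2.2.4, DESeq2 1.32 and deepTools 3.1.3 were used by the authors; their roles, the rule for merging peaks and any removal of duplicates are not given in the sources used here. Peak lengths had a median of 298 bp. Every count column matched 1 sample by its name.

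The genome build is not given in the sources used here. It was checked with a table of RefSeq genes of GRCh38.p14: 73.3% of 20037 protein-coding genes had a peak within 1 kb of an end of the gene, against 31.1% and 30.9% when peaks were shifted by 100 kb in either direction, so this gene table was used to place peaks. Positions are printed as the deposited table lists them. The gene table gives no strand, so a promoter, as planned, became a gene-end peak: one within 1 kb of either end of a protein-coding gene. No genome sequence was used here, so the planned search for NF-kB motifs and the correction for GC content were not run.

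Peaks at the start of chromosome 1 needed separate treatment. The first 11 peaks there, from position 30 to 16530, spanned about the length of the mitochondrial genome, judged by position alone, and the next peak started at 21504. The first 200 kb held 107 peaks and the following 200 kb held 14. All 109 peaks that start within 250 kb were therefore left out of library sizes and tests, a choice made after seeing the data; they held 17.9% to 25.4% of the counts of a library. The share in the first 11 peaks was 17.8% in control replicate 1, 17.7% in control replicate 2, 25.3% in sg1 replicate 1 and 25.2% in sg1 replicate 2. For control replicate 2, the shallowest library, the 95% Wilson interval of this share was 17.70% to 17.73%; it covers counting error only.

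The depth left was 21002477 and 15561701 counts in the control libraries and 43519018 and 38924086 in the sg1 libraries, with medians of 35, 26, 73 and 64 counts per peak. Log2 counts correlated across peaks at 0.952 between the control libraries, 0.980 between the sg1 libraries and 0.896 to 0.904 between groups; peaks are not independent replicates. Replicates differed by little more than paired cut ends can give. The mean chi-square per peak was 2.17 for the control pair and 2.08 for the sg1 pair. Independent counts give 1 and paired cut ends up to 2. At peaks under 100 counts over the pair it was 1.98 and 1.85, and at 1000 counts or more 2.46 and 2.42. Between groups it was 11.0 to 12.7. All 4 libraries were kept as separate replicates. The common dispersion was 0.0066, a biological coefficient of variation of 8.13%.

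Counts were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and the quasi-likelihood F test on group alone, and Benjamini-Hochberg adjustment at an FDR of 0.05. This left 184717 peaks; 5522 were too low to test. The SE of a log2 fold change was its size divided by the square root of F. TMM factors lay between 0.981 and 1.02. Gene lists, 20 in number with 503 entries and 478 different genes, were written before the data were examined from general knowledge, and all entries matched the gene table. Each gene was represented by its gene-end peak with the highest mean CPM. Lists were compared with all other such peaks by camera in limma 3.58.1 with a preset correlation of 0.01. They were compared again with an estimated correlation, and tested by fry. Shares of peaks at gene ends were compared by a two-sided Fisher's exact test. Other calculations used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6, and figures matplotlib 3.10.9.

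The peaks named in the text follow a rule written before the data were examined. It takes the CECR2 peaks; the gene-end peaks of CSF1, CXCL1, TNC, MMP2, VEGFA, RELA and NFKBIA; per direction the 8 genes, each by its gene-end peak with the smallest p, and the 4 other peaks with the largest fold change past the FDR, with both libraries of one group above both of the other and a mean scaled count of at least 30 in the higher group; and per list up to 3 members past the FDR with the smallest p, or else the member with the smallest p. Other peaks were chosen after their values were seen and are named as such, or complete a count of 5 or fewer.

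In data simulated from the real library sizes and means for this comparison, with 50 of 184717 peaks changed at each fold, edgeR recovered 2% of the 1.25-fold, 20% of the 1.5-fold, 44% of the 2-fold and 74% of the 4-fold changes, with 1 false call. So few changed peaks make the adjusted threshold stricter than in the real data. Camera recovered a simulated list of 30 lowered genes, and 5 of 100 unchanged lists had a p under 0.05. Peaks were simulated independently of each other, so this does not test the preset correlation. The alternatives tried were RLE size factors, library size only, loess offsets, DESeq2 1.42.0, no low-count filter and a mean count of at least 30. Others were the replicate number as a block, leaving out each library, an FDR of 0.01 and a minimum fold of 1.2. Gene-end windows of 0.5 and 2.5 kb, every peak within 10 kb of a gene end, and camera with an estimated correlation were also tried. Wherever peaks are given as within 10 kb of a gene, the distance is to either end of that gene. Some single-gene results among the list members are not reported here. Added after seeing the data were keeping the peaks at the start of chromosome 1, thinning all libraries to the smallest, centring log2 fold changes on medians of 5 Mb segments, and peaks within 10 kb with an estimated correlation.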

Results

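Chromatin accessibility was measured by ATAC-seq, which uses the Tn5 transposase to cut and tag open DNA, in LM2 cells. LM2 is a human breast cancer cell line derived from MDA-MB-231 and has a raised potential to form lung metastases. The 4 libraries, each from 50000 cells, formed 2 groups of 2 replicates: a control with a non-targeting guide and a CECR2 deletion made with guide sg1. Counts were given for 190348 peaks merged over the groups. The control libraries held 25610655 and 18950793 counts and the sg1 libraries 58341297 and 52150389. Peaks at the start of chromosome 1 that fall in the length range of the mitochondrial genome took 17.8% ± 0.0784 of the counts in the control and 25.2% ± 0.0314 in sg1 (SD, n = 2). The 109 peaks of that segment were left out, after which the sg1 libraries were 2.25 times as deep as the controls. Levels below are CPM after TMM scaling, as mean ± SD with n = 2 per group, and log2 fold changes are sg1 against control. No source says whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

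The comparison asked what loss of CECR2, a bromodomain protein that partners the ISWI chromatin remodellers, does to open chromatin in these cells; the series concerns metastasis and macrophage inflammatory responses. Loss of CECR2 went with the closing of many sites around NF-kB target genes, a shift that camera called at gene ends with its preset correlation but not with an estimated one. The IL1B, CXCL8 and TNFAIP3 loci held some of the largest losses in the genome, and 21 of the 34 tested NF-kB target genes were lower at their tallest gene-end peak. Peaks at gene ends were otherwise more often higher than lower in sg1. Differences between the libraries in signal over background, GC content or handling of nuclei stay open as causes of this lean. Of 184717 peaks tested with edgeR's quasi-likelihood test, 31041 were lower and 21269 higher in sg1 at an FDR of 0.05. The median change among called peaks was a log2 of -1.05 for lower and 0.87 for higher peaks, and 16377 lower and 9162 higher peaks changed more than 2-fold. Both libraries of one group lay above both of the other for 99.7% of the lower and 99.9% of the higher calls, against 63.7% of all tested peaks and 33.3% by chance. DESeq2 called 17866 peaks lower and 8475 higher. Without sg1 replicate 1 the edgeR calls were 19013 lower and 11524 higher, and without sg1 replicate 2 they were 18888 lower and 11147 higher.

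Accessibility at CECR2 itself gave no check of the deletion. The 5 tested peaks in the gene or within 1 kb of its end, on chromosome 22, were tallest at 17528944 to 17529762, with 178 and 106 counts in the control and 412 and 445 in sg1. This peak was at 7.78 ± 1.23 CPM in the control and 10.3 ± 1.40 in sg1 (log2 fold change 0.39, SE 0.15, adjusted p = 0.0430), a call that DESeq2 did not make (adjusted p = 0.179). The other 4 CECR2 peaks, starting at 17486421, 17501738, 17558258 and 17558459, had log2 fold changes between -0.61 and 0.45 and did not pass. Counts at those peaks were 9, 38, 15 and 74 in control replicate 1, 5, 33, 10 and 52 in control replicate 2, 17, 69, 22 and 148 in sg1 replicate 1, and 27, 54, 16 and 165 in sg1 replicate 2. Cut sites that lie outside an edited segment do not show whether the gene was edited.

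The NF-kB target list, fixed before the data were examined, had the largest shift of the 20 lists. NF-kB is the transcription factor family that drives inflammatory genes. Lists were read at the tallest gene-end peak of each gene. Of the 34 such peaks of NF-kB targets, 21 were lower, 2 (BCL3 and TRAF1) were higher and the rest did not pass; adjusted over the list alone, 22 were lower and 3 higher, and DESeq2 called 16 lower and 1 higher. The list's median log2 fold change was -0.31, against 0.15 over the tallest gene-end peaks of all genes (camera with the preset correlation, adjusted p = 9.66e-23). With an estimated correlation the camera p was 0.00977 and the adjusted p = 0.173, so the list was not called in that form. The estimate, 0.0107, was close to the preset 0.01, so a higher correlation between members is not what raised the p. For the macrophage, lung metastasis and haematopoietic lists below, which also lost their calls in that form, the estimate was negative. The rotation test fry in edgeR, which asks whether the members move one way and compares no list with other genes, gave an adjusted p of 0.0275. It passed 9 of 20 lists, 4 lower and 5 higher, so it does not set the NF-kB targets apart. TNIP1, which restrains NF-kB signalling, fell from 34.5 ± 1.57 to 10.9 ± 1.21 CPM (log2 fold change -1.65, SE 0.09, adjusted p = 1.76e-15). BCL2A1, an anti-apoptotic BCL2 relative, fell from 25.8 ± 2.99 to 6.87 ± 0.168 CPM (log2 fold change -1.92, SE 0.11). The tallest gene-end peak of IL1B, which encodes interleukin-1 beta, fell from 16.1 ± 1.84 to 3.33 ± 0.880 CPM (log2 fold change -2.29, SE 0.16). NFKBIA, the NF-kB inhibitor, fell from 45.9 ± 1.04 to 34.0 ± 2.75 CPM (log2 fold change -0.43, SE 0.07, adjusted p = 2.30e-05). RELA, which encodes an NF-kB subunit and is not on the list, rose from 20.4 ± 0.0944 to 24.5 ± 0.437 CPM (log2 fold change 0.27, SE 0.09, adjusted p = 0.0210), which DESeq2 did not call (adjusted p = 0.109). The other main gene-end peak of RELA, on chromosome 11 at 65662622 to 65663985 and chosen after its values were seen, rose from 18.2 ± 0.850 to 24.8 ± 3.32 CPM (log2 fold change 0.44, SE 0.10, adjusted p = 0.000707).

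Peaks around NF-kB targets were more often lower than peaks near genes in general. Of 234 tested peaks within 10 kb of an end of these genes, 113 (48.3%) were lower and 12 (5.13%) higher. Among all 60978 tested peaks that close to a gene end, 12.4% were lower and 14.4% higher. Without the tallest gene-end peak of each target, 92 of 200 were lower and 10 higher. Of the 34 genes with such a peak, 32 had at least 1 lower peak. TRAF1, higher at its tallest gene-end peak, had 8 lower and 1 higher of 14 peaks within 10 kb. BCL3, also higher at its tallest, had 1 lower and 1 higher of 8. The median over the 234 peaks was -0.37 (camera, adjusted p = 1.07e-29; adjusted p = 0.0447 with an estimated correlation). At TNFAIP3, which encodes the NF-kB inhibitor A20, the tallest gene-end peak did not pass (log2 fold change -0.12), while a peak on chromosome 6 at 137883428 to 137883881 fell from 3.14 ± 1.00 to 0.0593 ± 0.0121 CPM (log2 fold change -5.60, SE 0.49, adjusted p = 7.84e-11). At CXCL8, which encodes interleukin-8, the tallest gene-end peak fell by 0.44 on the log2 scale, and another at 73744595 to 73745273 on chromosome 4 fell from 11.7 ± 1.47 to 0.553 ± 0.0788 CPM (log2 fold change -4.39, SE 0.23). All 6 tested peaks within 10 kb of CXCL8 were lower, as were 7 of 10 at NFKBIA, 7 of 8 at IL1B, 5 of 8 at TNFAIP3 and all 3 at BCL2A1. These loci were singled out after their values were seen. Along chromosome 2 from 112764035 to 112840024, which spans IL1A and IL1B, 15 of 20 tested peaks were lower and 0 higher (0 also at an unadjusted p under 0.05 and by DESeq2, which called 11 lower). Along the chemokine cluster from CXCL8 to CXCL2, at 73735263 to 74109896 on chromosome 4, 25 of 51 tested peaks were lower and 5 higher.

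**Figure D1:**
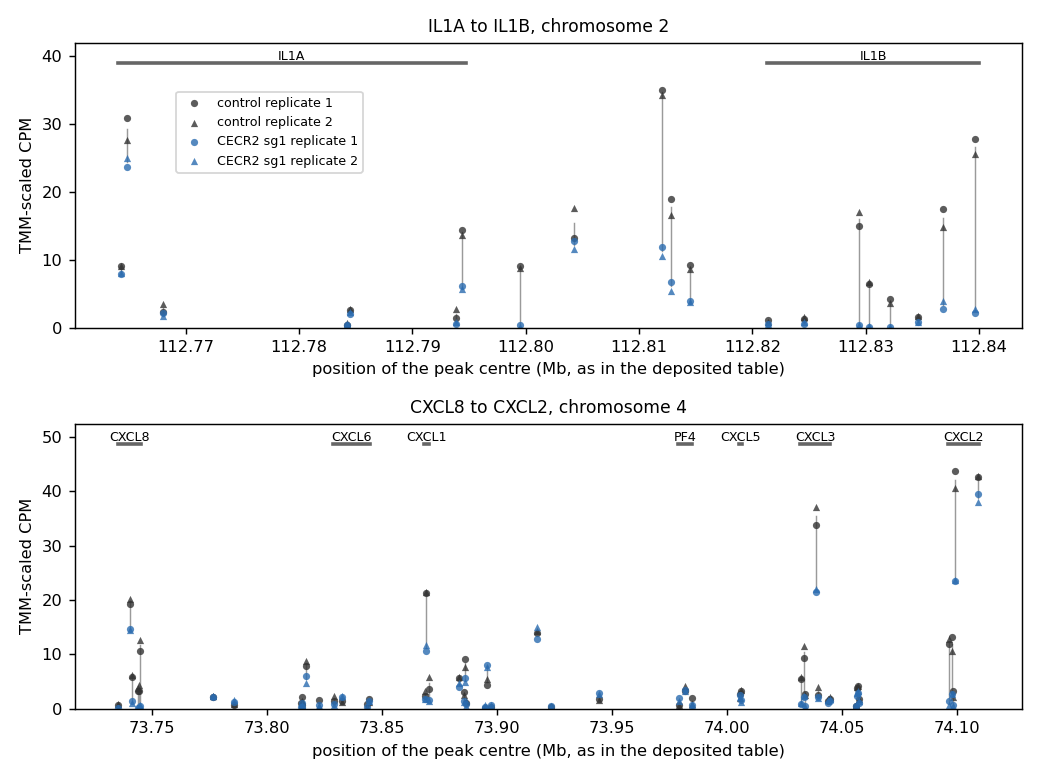
TMM-scaled CPM (y axis) of every tested peak by position (x axis, Mb) in the IL1A to IL1B and CXCL8 to CXCL2 regions, with 1 point per library and grey lines joining the group means. Horizontal bars span the tested peaks within 10 kb of an end of each named gene. Control points lie above sg1 points at the 15 lower peaks of the IL1 region.

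The list of secreted factors that act on macrophages also holds CD47, which encodes a cell-surface protein. Of its 24 tested gene-end peaks, 11 were lower and 3 (MIF, CD47 and TGFB1) higher. Adjusted over the list alone, 12 were lower and 3 higher. The median was -0.17 (camera, adjusted p = 1.32e-10; adjusted p = 0.173 with an estimated correlation). CSF3, which encodes the granulocyte growth factor G-CSF and shares its peak with MED24, fell from 47.5 ± 2.09 to 14.1 ± 0.443 CPM (log2 fold change -1.76, SE 0.08, adjusted p = 5.22e-18). The chemokine gene CCL20 fell from 81.1 ± 2.41 to 47.5 ± 0.447 CPM (log2 fold change -0.77, SE 0.06), and CXCL2 from 42.1 ± 2.18 to 23.6 ± 0.163 CPM (log2 fold change -0.84, SE 0.08). The NF-kB list holds 8 of the 32 genes of this list; among the 17 tested members it does not hold, 4 (CSF3, PLAU, IL10 and CCL5) were lower and 3 higher, with a median of -0.11. CSF1, the macrophage growth factor gene, did not pass at its tallest gene-end peak, with 19.99 ± 2.26 CPM in the control and 18.7 ± 1.08 in sg1 (log2 fold change -0.11, SE 0.10, adjusted p = 0.433). A peak inside CSF1, at 109926879 to 109927349 on chromosome 1, fell from 9.89 ± 0.779 to 2.05 ± 0.471 CPM (log2 fold change -2.27, SE 0.19); it was chosen after its values were seen. Of the 9 tested peaks within 10 kb of CSF1, 2 were lower and 2 higher, the latter at 109904513 to 109904843 and 109931244 to 109931394.

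The lung metastasis signature, genes known for their link to lung colonisation by this line, had 7 lower and 3 higher among 19 tested gene-end peaks, also when adjusted over the list alone. Its median was -0.09 (camera, adjusted p = 0.000647; adjusted p = 0.343 with an estimated correlation). The chemokine gene CXCL1 fell from 21.4 ± 0.129 to 11.2 ± 0.792 CPM (log2 fold change -0.94, SE 0.10, adjusted p = 8.76e-09). MMP1, a collagenase gene, fell from 5.68 ± 0.561 to 1.88 ± 0.204 CPM (log2 fold change -1.60, SE 0.22), and IL13RA2, a decoy receptor gene, from 2.63 ± 0.150 to 0.659 ± 0.0367 CPM (log2 fold change -1.99, SE 0.32). The 3 higher members were ID1, LY6E and FSCN1. NF-kB targets made up 3 of its 21 genes, and the 16 other tested members had 4 lower and 3 higher peaks with a median of -0.02. TNC, MMP2 and VEGFA encode a matrix protein, a gelatinase and an angiogenic factor. They did not pass at their tallest gene-end peak, with log2 fold changes of -0.09, -0.01 and -0.03. The MMP2 peak had 19 and 23 counts in the control libraries. Within 10 kb of the ends of these genes, 3 of 13, 3 of 15 and 1 of 8 tested peaks were lower, and 0, 1 and 0 higher.

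Among the 5 lists for other cell types or differentiation states, the haematopoietic list was called by camera, with 4 lower and 0 higher of 14 tested gene-end peaks (5 and 0 adjusted over the list alone; median -0.16; camera, adjusted p = 0.00525; adjusted p = 0.367 with an estimated correlation). DESeq2 called 2 of its peaks lower. The list was not called by camera over peaks within 10 kb of the ends of its genes (adjusted p = 0.513). The lower members were CD68, RUNX3, CD3E and LAPTM5, with the peak shared by CD68 and EIF4A1 falling from 48.5 ± 2.02 to 33.6 ± 1.89 CPM (log2 fold change -0.53, SE 0.07). Of 22 epithelial gene-end peaks, 7 were higher and 1 lower (8 and 1 adjusted over the list alone). KRT7, a simple-epithelium keratin, rose from 7.21 ± 1.80 to 16.2 ± 0.00334 CPM (log2 fold change 1.19, SE 0.13), and the tight junction gene CLDN3 from 4.80 ± 0.872 to 11.2 ± 1.42 CPM (log2 fold change 1.24, SE 0.16). ELF3, an epithelial transcription factor, went the other way (log2 fold change -1.66, SE 0.14, adjusted p = 2.66e-11). The mesenchymal and matrix list split, with 4 lower, among them COL6A2 (log2 fold change -1.43) and CALD1 (-1.14), and 7 higher, among them COL5A1 (0.65), of 26 peaks, the same counts as over the list alone, while DESeq2 called 3 lower and 4 higher. Luminal breast genes had 1 higher (GATA3, log2 fold change 0.76) and 1 lower of 15, and 1 and 0 adjusted over the list alone. None of 7 fibroblast and endothelial peaks passed with edgeR, over all peaks or over the list alone; at an unadjusted p under 0.05, 2 were higher and 0 lower, and DESeq2 called 0. KDR had the smallest p, with a log2 fold change of 0.30 and an adjusted p of 0.0692. The epithelial, mesenchymal, luminal and fibroblast lists were not called by camera, with adjusted p between 0.520 and 0.706.

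Camera called none of the other 12 lists, with adjusted p between 0.200 and 0.983 over those 12. Of these, fry passed the TGF-beta, ribosomal protein, hypoxia, ISWI and AP-1 lists, all higher (adjusted p between 0.0275 and 0.0485). Fry tests against no change, not against other genes. In that order the list medians were 0.30, 0.18, 0.23, 0.17 and 0.08, against 0.15 over the tallest gene-end peaks of all genes. TGF-beta signalling had the highest median, 0.30, with 12 of 24 peaks higher and 0 lower (adjusted p = 0.200), led by SMURF1 (log2 fold change 0.95), SMAD6 (0.65) and ID3 (0.53). Ribosomal proteins had 14 higher and 1 lower of 40, led by RPS14 (0.54), RPS19 (0.41) and RPL12 (0.39), and hypoxia and glycolysis genes 10 higher and 1 lower of 24, led by ANKRD37 (0.48), ALDOC (0.86) and ENO1 (0.48). ISWI remodellers and partners had 4 higher and 0 lower of 11, with BAZ1B (0.53), RBBP4 (0.50) and BPTF (0.29) past the threshold. YAP and TEAD targets had 6 higher and 1 lower of 26, with F3 (0.50), TEAD1 (0.44) and ASAP1 (-0.25). Lists that split were AP-1 and immediate early genes (7 higher and 3 lower of 25; JUND 0.64, FOSL1 -0.32, KLF4 0.38), bromodomain genes (7 and 3 of 20; TAF1 -0.71, TRIM24 0.34, ATAD2 0.37) and the cell cycle (7 and 4 of 30; CCND1 -0.45, E2F1 0.41, CDC25C 0.49). The stress and unfolded protein response had 8 higher and 5 lower of 24 (HSPB1 1.11, TRIB3 0.58, SRXN1 0.52), and p53 targets 6 and 5 of 22 (TP53I3 -0.51, MDM2 0.53, CCNG1 -0.32). The interferon response had 3 higher and 2 lower of 25 peaks (the peak shared by RSAD2 and CMPK2 -0.77, USP18 0.63), and antigen presentation 0 higher and 3 lower of 16 (the peak shared by TAP1 and PSMB9 -0.22). Adjusted over the list alone, higher and lower counts were 12 and 0 for TGF-beta, 14 and 1 for ribosomal proteins, 10 and 1 for hypoxia, 5 and 0 for ISWI, 6 and 1 for YAP, 9 and 3 for AP-1, 8 and 3 for bromodomain, 7 and 5 for cell cycle, 8 and 5 for stress, 6 and 6 for p53, 3 and 2 for interferon and 0 and 3 for antigen presentation genes. DESeq2 called fewer, with higher and lower counts of 10 and 0 for TGF-beta, 8 and 0 for ribosomal proteins, 5 and 1 for hypoxia, 3 and 0 for ISWI, 2 and 0 for YAP, 6 and 1 for AP-1, 5 and 2 for bromodomain, 5 and 4 for cell cycle, 6 and 3 for stress, 1 and 2 for p53, 1 and 2 for interferon and 0 and 1 for antigen presentation genes. With library size only, edgeR called 10 YAP, 5 interferon and 2 antigen presentation peaks higher and 2 p53 peaks lower. The peaks given for FOSL1, ANKRD37, ALDOC, CCND1, E2F1, CDC25C, RPL12, RBBP4 and ATAD2, and that of TGFB1 above, lie at an end of another gene too. At an unadjusted p under 0.05 edgeR found 0 lower TGF-beta and 0 lower ISWI peaks, 0 higher haematopoietic and 2 higher antigen presentation peaks, and DESeq2 called 0 in each of these 4 cases.

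Apart from lists, each gene was taken by its gene-end peak with the smallest p. The 8 genes with the largest losses at that peak were TNFAIP3, IL1B, FBLN1, SELENOK, CXCL8, SERPINB7, C3 and IGSF3. The IL1B peak, on chromosome 2 at 112828911 to 112829854, fell from 15.9 ± 1.44 to 0.406 ± 0.000736 CPM (log2 fold change -5.27, SE 0.21, adjusted p = 1.97e-19). The complement gene C3 fell from 13.9 ± 0.935 to 1.02 ± 0.353 CPM (log2 fold change -3.78, SE 0.20), and the other 4 fell by 3.71 to 4.94 on the log2 scale. Low counts leave several of these sizes uncertain: in sg1 replicates 1 and 2, FBLN1 had 4 and 1 counts, SELENOK 6 and 0, SERPINB7 6 and 0, and IGSF3 8 and 20. With 1 library left out the log2 fold changes ran from -6.004 to -4.35 for FBLN1, -8.54 to -3.71 for SELENOK, -7.76 to -2.93 for SERPINB7 and -4.57 to -3.11 for IGSF3. DESeq2 did not call SERPINB7 (adjusted p = 0.0730). The 8 genes with the largest gains, taken the same way, were SORCS1, TMEM132E, PEX11A, LRRC17, FNDC8, CLDN4, GTF2I and LIFR, with log2 fold changes of 2.59 to 3.43. CLDN4, a tight junction gene, rose from 0.682 ± 0.135 to 4.47 ± 0.549 CPM (log2 fold change 2.68, SE 0.29, adjusted p = 1.26e-08), and LIFR, the receptor gene for leukaemia inhibitory factor, from 0.399 ± 0.358 to 2.22 ± 0.275 CPM (log2 fold change 2.59, SE 0.42). Of these 8 genes all but CLDN4 had 1 to 10 counts in each control library, and with 1 library left out the log2 fold change ran from 2.96 to 4.48 for SORCS1, 2.02 to 4.36 for PEX11A, 2.10 to 4.42 for LRRC17, 1.99 to 3.70 for FNDC8, 1.74 to 4.44 for GTF2I and 1.76 to 3.90 for LIFR. DESeq2 did not call GTF2I (adjusted p = 0.0756), which has near-identical copies nearby that make its counts uncertain.

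The 4 largest gains away from gene ends had 0 counts in both controls. Against a floor of 3 counts over the control group they were at least 28.3-fold higher on chromosome 17 at 71163524 to 71163889 (nearest gene end SOX9, 957 kb away), at least 18.2-fold on chromosome 8 at 58257239 to 58257684 (FAM110B, 108 kb), at least 16.7-fold inside FRMD4A (chromosome 10, 14254413 to 14254726) and at least 12.7-fold inside LAMB1 (chromosome 7, 107952612 to 107952776). The 4 largest losses included a peak on chromosome 6 at 138017245 to 138017494, 71.0 kb from PERP, with 0 counts in both sg1 libraries and at least a 28.0-fold lower level. The other 3 had 2, 2 and 3 counts over the sg1 group, and the control level was higher by a ratio of 120.0 (95% exact interval 32.4 to 1004) on chromosome 12 at 90281245 to 90281637 (nearest gene end ATP2B1, 572 kb), 69.9 (18.5 to 590.6) inside SUCLG2 on chromosome 3 at 67386509 to 67386807, and 58.3 (19.2 to 288.9) on chromosome 6 at 132736273 to 132736612 (VNN2, 7.26 kb). Intervals and floors cover counting error only.

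Position relative to genes set the 2 directions apart. Gene-end peaks, those within 1 kb of either end of a protein-coding gene, made up 5.60% of the lower peaks (1739 of 31041) against 14.4% of the others (odds ratio 0.352), and 23.8% of the higher peaks (5063 of 21269) against 11.5% of the others (odds ratio 2.40). Fisher's exact test gave p-values too small for double precision in both cases, and peaks are not independent replicates. Of 23891 gene-end peaks 7.28% were lower and 21.2% higher, with a median log2 fold change of 0.17. Of 79786 peaks elsewhere in genes 17.8% were lower and 10.1% higher (median -0.02), and of 81040 between genes 18.6% were lower and 10.1% higher (median -0.02). The libraries of the sg1 group were also the deeper ones and those with the larger share of counts in the mitochondrial range.

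**Figure D2:**
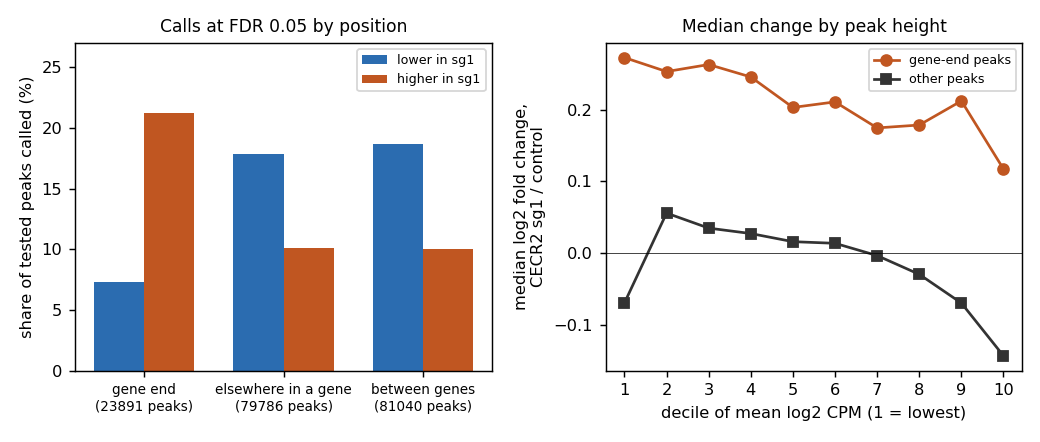
Left, share of tested peaks called lower or higher in sg1 at an FDR of 0.05 (y axis, %) by position relative to protein-coding genes. Right, median log2 fold change (y axis) of gene-end and other peaks in each decile of mean log2 CPM (x axis); the gene-end median is the higher one in all 10 deciles.

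Chromosomes differed in their balance of losses and gains. The median log2 fold change per chromosome ran from -0.27 on X, where 27.2% of 5029 peaks were lower and 4.73% higher, to 0.21 on chromosome 7, where 11.7% of 9784 peaks were lower and 21.4% higher. Within X the shift was largest from 65 to 70 Mb, with a median of -0.76 and 83 of 149 peaks lower. TAF1, among the lower list members named above, lies on X at 71365614 to 71366841, in the segment from 70 to 75 Mb with a median of -0.54. After centring on segments its log2 fold change was -0.17 (adjusted p = 0.109), against -0.71 before. Of the named peaks on chromosome 7, those of CLDN3, CLDN4, BAZ1B, GTF2I, HSPB1, SMURF1, LRRC17, TRIM24 and LAMB1 rose and that of CALD1 fell. On that chromosome 8 of 11 peaks were higher from 74400735 to 74484001, and 8 of 12 from 75114856 to 75192100, with 0 lower. These windows were chosen after their values were seen. How far the named gains there are regional was not settled. Over 574 segments of 5 Mb with at least 50 peaks, the medians had an SD of 0.17.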

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

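Both tests in this part were chosen after the result was seen. The sg1 libraries carried 25.2% ± 0.0314 of their counts in the 11 peaks at the start of chromosome 1, from position 30 to 16530, against 17.8% ± 0.0784 in the control (SD, n = 2 each), a signal outside the peaks compared in the report. Per count elsewhere this is 1.56 times the control level. Peaks over annotated nuclear copies of mitochondrial genes share reads with mitochondrial DNA, and the 42 tested ones had a median log2 fold change of 0.92, with 27 higher and 1 lower. The direction is the one that mitochondrial DNA placed on chromosome 1, and more abundant in the sg1 libraries, would give. The size is larger than the rise of the 11 peaks themselves, a log2 of 0.64. Shared reads with that rise do not by themselves account for it, so the origin of these counts is not settled. Depth alone is argued against, because the control libraries, which differ 1.35-fold in depth, differed by 0.111 percentage points in this share, against 7.47 points between groups. Whether the larger share reflects the deletion, the state of the cells or the handling of nuclei was not tested.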

How the results depend on the processing

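Keeping the peaks at the start of chromosome 1, thinning, centring on 5 Mb segments, and peaks within 10 kb with an estimated correlation were alternatives chosen after seeing the data. Apart from the settings that follow, the lower peaks numbered 22139 to 31411 and the higher peaks 14370 to 25028. DESeq2 called 17866 lower and 8475 higher peaks, of which 17857 and 8475 were called in the same direction by edgeR, a minimum fold of 1.2 left 22753 lower and 12509 higher peaks, and an FDR of 0.01 left 21484 and 11458; the last 2 are stricter by construction, and the cause was not tested for DESeq2. Leaving out 1 library gave 18888 to 29467 lower and 11147 to 20243 higher peaks, with more lost without an sg1 library, for a cause not tested; the lone library left in a group is then assumed to vary like the others. The odds ratio of gene-end position stayed between 0.306 and 0.418 for lower and 1.78 and 2.99 for higher peaks. Of the lists, camera called 4 or 5 in every setting except 0 with an estimated correlation and 1, the NF-kB targets, within 10 kb with an estimated correlation. The NF-kB median lay between -0.37 and -0.23 with an adjusted p of at most 0.0447, except with the estimated correlation, where it was -0.31 with an adjusted p of 0.173. Among the 19 other lists, 3 were no longer called with an estimated correlation, the epithelial list was gained and the haematopoietic list lost within 10 kb, and p53 targets were gained by centring. Of 88 named peaks, 73 kept direction and side of the threshold in every setting where they were tested. After centring, 9 named peaks were no longer called, with TAF1 among them and the others not named here. Centring gave 30489 lower and 17523 higher peaks in all. The spread of chromosome medians, 0.48, is the same with library size only, which shifts all peaks alike. The replicate numbers do not pair the libraries (correlation of same-numbered deviations -0.000258), and a replicate block gave 30358 lower and 21218 higher peaks and changed no list call. The GC corrections, with and without a block, and the motif alternatives were not run. In simulated data 44% of 2-fold and 20% of 1.5-fold changes were recovered, under a stricter threshold than in the real data, as far fewer peaks changed.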

Other observations

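Peaks near epithelial genes were more often higher than lower. Within 10 kb of the ends of the 27 epithelial genes, 43 of 162 tested peaks were higher and 18 lower. Their median log2 fold change was 0.29 (camera, adjusted p = 0.0483, or 0.380 with an estimated correlation). Luminal breast genes had 21 higher and 10 lower of 100 peaks (median 0.31, adjusted p = 0.203), and TGF-beta signalling genes 48 higher and 21 lower of 210 (median 0.18, adjusted p = 0.172). TGFB1, the gene of the main TGF-beta ligand, had 6 higher and 0 lower of 11 tested peaks within 10 kb of its ends. It was chosen after its values were seen.

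Losses also came in clusters outside the fixed lists. The windows and segments named here were chosen after their values were seen. Among 10109 windows of 100 kb with at least 8 tested peaks, the highest shares of lower peaks were 11 of 11 on chromosome 12 (127230563 to 127293859) and 9 of 9 on chromosome 9 (81902652 to 81970306, near SPATA31D3 and SPATA31D4). The 15 windows with the highest shares also held the one at IL1B (16 of 20), the one at CXCL8 (14 of 18) and the one at SOD2 (8 of 10). The highest share of higher peaks was 8 of 9 at ATP10A on chromosome 15 (25830863 to 25892461), and the window at HAVCR1 and HAVCR2 on chromosome 5 had 6 of 9. On X, the 5 Mb segments from 45 to 60 Mb had medians of -0.59, -0.72 and -0.60. In the 415 segments with at least 20 peaks of each kind, the medians of gene-end and other peaks correlated at 0.815 across segments, which are not independent replicates.

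The tests in the following paragraphs had their predictions written before the result was seen; the settings they use, thinning and 5 Mb centring, were added after seeing the data. Gene-end peaks leaned higher and other peaks lower in sg1. A difference in signal over background between libraries was predicted to shift peaks of like height alike. Within deciles of mean CPM the gene-end median exceeded the other by 0.230 on average and in all 10 deciles. However, peaks ran from 151 to 2820 bp and their lengths were not matched. At the same CPM, background could weigh differently on short and long peaks, so this cause stays open. A difference in depth is argued against, since with all libraries thinned to the smallest the odds ratio of gene-end position among higher peaks was 2.37. GC content, which differs between gene ends and other sites, and the handling of nuclei stay open and were not tested, as does an effect of the deletion.

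Peaks near NF-kB targets were more often lower than higher in sg1, which may reflect a change in NF-kB-driven enhancers, as a hypothesis. A change in copy number that covers most of a 5 Mb segment would vanish on centring. The median of the 234 peaks within 10 kb of a gene end was -0.36 after centring, against -0.37 before, which argues against such wide changes for these peaks. At the tallest gene-end peaks the list median moved further, from -0.31 to -0.23. The list was still called there by camera with the preset correlation (adjusted p = 9.39e-21), but wide changes could account for part of that shift. Centring does not remove changes confined to a small part of a segment, so those stay open. A general loss of peaks away from gene ends does not account for it either: the 141 list peaks away from gene ends had a median of -0.39, while 10000 random gene sets matched on peak number and mean CPM had medians from -0.10 to 0.17 in 95% of sets, and 0 of them was as low. GC content and a difference between the cultures unrelated to CECR2 stay open, since the data hold 1 guide and 2 libraries per group. Whether NF-kB motifs mark the lost peaks was not analysed here.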
